A study of Homo sapiens with 6 samples.

How the data were processed

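The series holds 6 RNA-seq libraries of BE(2)-M17 cells, 3 from control cells and 3 from cells with a CRISPR-Cas9 knockdown of LINC00894, and each library was assigned to its group by the sample titles. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was taken with oligo-dT beads and fragmented, and cDNA was made with random primers and a plain second strand, which keeps no record of strand. HISAT2 is named in the submitters' processing notes, with no version. The read counter, the genome build, the annotation release, the test behind the deposited comparison and the guide sequences are not given in the sources used here.

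The authors deposited a table of 40111 genes whose columns per library hold FPKM, judged from the values, since the columns sum to between 271337 and 276464 and each gene's values are whole multiples of what 1 read is worth. The same table gives, per the file headers, the authors' mean read signal of each group, which follows from the reads with 1 size factor per library, a log2 fold change of knockdown over control, and a p-value and adjusted p-value per gene. A second deposited table holds the log2 fold changes and p-values of a subset of these genes. All 6 columns of per-library values matched a sample title, and 0 did not.

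Whole reads per gene were recovered from the ratios of the deposited FPKM values and the group means. Within a tolerance of 0.1 read, 100% of the values above 0 came out whole, and the recovered reads gave the deposited group means, within 1%, or within 0.01 for means under 1, in 100% of genes. The gene lengths this implies lay within 5% of the union of exons in GENCODE 29 for 80.7% of 18899 genes with at least 100 reads. For LINC00894 the implied length was 9019 bases against 6323 in GENCODE 29, so the authors' gene model there differs from that release. Coordinates are from GENCODE 29 on GRCh38, which held 96.3% of the gene IDs, and symbols are those of the deposited table. Depth ranged from 22898079 to 48089716 assigned reads per library. In a gene model of 1 kb, 1 read was worth between 0.0208 and 0.0437 FPKM.

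Counts of reads had been planned as the input of a negative binomial test, but the deposited unit was FPKM, so the main test became limma (version 3.58.1, R 4.3.3) with a mean-variance trend on log2(FPKM + 0.1). The planned TMM scaling and count-based filter (filterByExpr) were dropped with the planned test, and the scaling of FPKM by total reads was kept. The negative binomial test was not run on the recovered reads either. Fold changes are therefore on the log2(FPKM + 0.1) scale, which understates the change of low genes. Genes with at least 0.5 FPKM in at least 3 of the 6 libraries were tested, 18548 in all, with group as the only term, two-sided p-values and Benjamini-Hochberg adjustment over all genes tested. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists. Those lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule was written for the planned test's p-values and was applied to those of limma. The filter at 0.5 FPKM, the pseudocount of 0.1 and the recovered reads as input were set once the deposited unit was known. In addition, 4 marker lists (red cell, neutrophil and monocyte, lymphocyte, and replication-dependent histone genes) were added afterwards. The rule named LINC00894, ATF3, the 10 largest rises and 10 largest falls with an adjusted p under 0.05, a mean CPM of at least 5 in the higher group, no overlap between groups and a symbol other than a clone or locus identifier, up to 4 members of each list with the smallest p, and chromosome X neighbours past the test. Other members that passed are named where a list's count is given. Single-gene results of some list members are not reported here, though these genes stayed in every fit and every list count. Python 3.11.15 with pandas 2.3.3 recovered the reads.

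Tested on simulated data drawn from these libraries' means and depths with 200 changed genes among 18548, limma on log2 FPKM recovered 61% of the genes changed 2-fold and 99% of those changed 4-fold, with 10 false calls among 170. Limma-voom recovered 77% and 100%, with 6 false calls among 183. Camera called the 1 list raised 1.4-fold and 0 of the other lists. Genes were drawn independently and no simulated library stood apart within its group. The simulation therefore cannot show how camera or limma behaves when genes are correlated. No pair of libraries agreed within sampling noise: the chi-square per gene, over genes with at least 20 reads in both libraries together, was 4.1 for the closest pair and 13.3 for controls 2 and 3.

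The alternatives were median-of-ratios size factors, no filter on low values, a filter at a CPM of 1 in at least 3 libraries, limma-voom on the recovered reads, an adjusted p under 0.01, the replicate number as a block, each library left out in turn, and, for the lists, an estimated correlation and fry. Pseudocounts of 1 and 0.01 FPKM and a fit with no mean-variance trend were added after the data were seen. Calls shared with the authors' deposited comparison were counted without a test.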

Results

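Messenger RNA was profiled by RNA-seq in BE(2)-M17 cells, a human neuroblastoma cell line with neuroblast character, in 3 control libraries and 3 libraries from cells in which LINC00894, a long non-coding RNA, was knocked down with a CRISPR-Cas9 vector. The comparison asks which genes change when LINC00894 is lowered, and whether ATF3, a stress-induced transcription factor that the study names as its target, is among them. Values were FPKM. The reads behind them, worked out from the deposited values, came to 29276653, 48089716 and 43219009 assigned reads in controls 1, 2 and 3 and to 22898079, 28339105 and 28782977 in knockdowns 1, 2 and 3. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

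LINC00894 was lower in all 3 knockdown libraries than in any control. It stood at 2.00, 2.24 and 2.21 FPKM in controls 1, 2 and 3 and at 1.10, 1.30 and 0.867 FPKM in knockdowns 1, 2 and 3, from 528, 970 and 863 reads and from 228, 333 and 225 reads. The log2 fold change was -0.93 (SE 0.17, n = 3 per group), with an adjusted p of 0.0406 in limma. The gene (ENSG00000235703) lies on chromosome X from 149938628 to 150224580 on the plus strand of GRCh38, where GENCODE 29 annotates it as an antisense RNA. On the log2(FPKM + 0.1) scale it was 1.91-fold lower in the knockdown, and with a pseudocount of 1 FPKM, chosen after the data were seen, its log2 fold change was -0.60. Its 5′ end overlaps the 5′ end of EOLA2, a protein-coding gene on the minus strand (149929527 to 149938811). EOLA2 fell by 0.55 on the log2 scale (SE 0.10, adjusted p = 0.0402 in limma). The library protocol marks no strand, so reads in the overlap of LINC00894 and EOLA2 cannot be assigned to one of these genes. The guide sequences are not given, so the target site cannot be placed relative to EOLA2.

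ATF3 fell with LINC00894. It measured 239, 352 and 415 FPKM in the controls and 163, 155 and 167 FPKM in the knockdowns, a log2 fold change of -1.01 (SE 0.20, n = 3 per group, adjusted p = 0.0415 in limma). All 3 knockdown libraries lay below all 3 controls, and the lowest control was control 1. ATF3 (ENSG00000162772) is a protein-coding gene on chromosome 1, from 212565334 to 212620777 on the plus strand of GRCh38. Without control 1 the limma adjusted p was 0.00067 for ATF3 and 0.00864 for LINC00894. Without any single one of the other 5 libraries neither gene passed the threshold, with limma adjusted p between 0.0983 and 0.17 for ATF3 and between 0.11 and 0.17 for LINC00894. With no filter on low values neither passed in limma, at adjusted p of 0.0734 for LINC00894 and 0.0771 for ATF3.

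**Figure D1:**
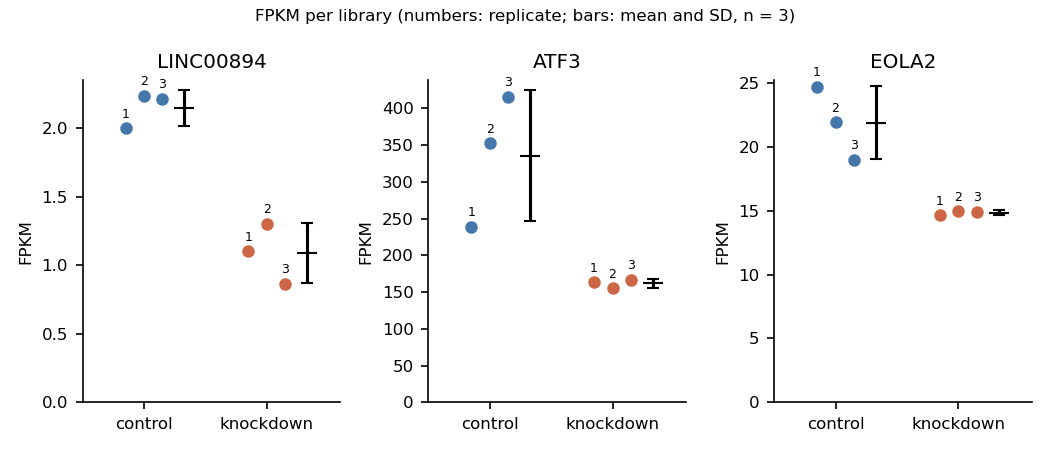
FPKM of LINC00894, ATF3 and EOLA2 (y axis, from 0) in each control and knockdown library, with the replicate number beside each point and bars for the mean and SD of the 3 libraries. LINC00894 lies between 2.00 and 2.24 FPKM in the controls and between 0.867 and 1.30 FPKM in the knockdowns.

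**Figure D2:**
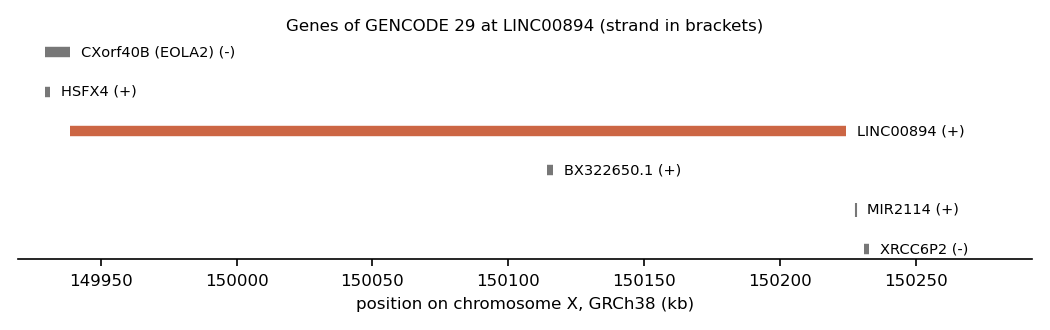
Genes annotated in GENCODE 29 at LINC00894 on chromosome X of GRCh38, with position in kb on the x axis and the strand in brackets. The minus-strand gene EOLA2, named CXorf40B in that annotation, has its 5′ end at 149938811, within the 5′ end of LINC00894, which starts at 149938628. A vertical tick marks a gene too short to draw to scale.

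Across the transcriptome, 768 genes rose and 382 fell in the knockdown among 18548 genes tested (limma, adjusted p under 0.05). At least 2-fold changes made up 223 of these, 171 higher and 52 lower. With no filter on low values limma called 25 rises and 17 falls, with no mean-variance trend it called 65 and 26, and with a pseudocount of 1 FPKM the 2-fold count was 112, the last 2 settings chosen after the data were seen. Protein-coding genes accounted for 628 of the rises and 285 of the falls. The smallest adjusted p was 0.0237, while 6050 genes had an unadjusted p under 0.05. The groups did not overlap in 7089 genes, or 38.2%, where chance gives 10%. The balance of rises and falls depended on the scaling: with median-of-ratios size factors 338 genes rose and 495 fell, so that 40.6% of calls were higher in place of 66.8%, and the median of all genes moved from 0.07 to -0.05. Leaving out control 1 gave 5187 rises and 2906 falls, including all 1150 genes called with it. In 60.8% of genes tested, control 1 was nearer to the knockdown mean than to the mean of controls 2 and 3. Leaving it out therefore removes spread among the controls and counts what it shares with the knockdowns as a group difference. Results without control 1, here and for other genes and lists, are no independent support for an effect of the knockdown. Limma-voom on the reads of all 6 libraries called 3130 genes, including 1091 of the 1150. Leaving out any one of the other 5 libraries left 0 genes past the limma threshold, with between 3676 and 4530 genes at an unadjusted p under 0.05, and limma-voom on the recovered reads then called 15 genes without control 3 and 0 without each of the other 4.

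Among genes with a mean CPM of at least 5 in the higher group, no overlap between groups and a symbol other than a clone or locus identifier, the largest rises included globin and histone genes. HBB, the beta chain of adult hemoglobin, had a log2 fold change of 5.80 (SE 1.18), HBA2 one of 5.59 (SE 0.91) and HBA1 one of 3.75 (SE 0.34), with limma adjusted p of 0.0456, 0.0379 and 0.0284. HBA2 read 0.578, 0.101 and 2.97 FPKM in controls 1, 2 and 3 and 46.8, 34.7 and 28.4 FPKM in the knockdowns. Without control 3 the log2 fold changes of HBB and HBA2 were 7.24 and 6.61, and without control 2 they were 4.88 and 4.64. HBA1 and HBA2 encode the same alpha chain and are nearly identical, so the split of reads between them is uncertain. The replication-dependent histone genes H4C5, H3C6 and H2BC5 rose by 2.80, 2.17 and 2.07 on the log2 scale, and members of this family also resemble each other in sequence. Control 1 was the highest control for these histone genes, with H2BC5 at 7.76 FPKM against 3.46 and 3.16 FPKM in controls 2 and 3 and between 15.4 and 23.8 FPKM in the knockdowns. KLKP1, a kallikrein pseudogene, rose by 2.68 on the log2 scale, ZSCAN12P1, a zinc finger pseudogene, by 2.09, CFAP44, a cilium and flagellum gene, by 1.98, and FOSB, an immediate early transcription factor, by 1.84. CFAP44 stayed low, with 0.262 ± 0.153 FPKM in the controls and 1.25 ± 0.0602 FPKM in the knockdowns (SD, n = 3). Control 1 was also the highest control for KLKP1, ZSCAN12P1, CFAP44 and FOSB, with FOSB at 3.74 FPKM against 1.27 and 1.35 FPKM in controls 2 and 3, and without control 1 the log2 fold change of KLKP1 was 3.32.

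Under the same rule, the deepest fall was that of INHBE, an inhibin beta subunit, which had a log2 fold change of -2.42 (SE 0.45), from 22.0 ± 11.5 FPKM in the controls to 3.58 ± 0.614 FPKM in the knockdowns (SD, n = 3). ISG15, a ubiquitin-like interferon-induced protein, fell by 1.90 on the log2 scale, IFNL1, a type III interferon, by 1.77, and G0S2, an inhibitor of triglyceride breakdown, by 1.73. ASNS, which makes asparagine, had -1.40, the chemokine scavenger ACKR4 -1.38, the polyamine acetyltransferase SAT1 -1.35, TXNIP, the thioredoxin-interacting protein, -1.29, the matricellular protein CCN1 -1.28 and SLC7A11-AS1, an antisense RNA at the cystine transporter gene, -1.27. SLC7A11 itself fell by 0.83 on the log2 scale, and without strand the reads of the SLC7A11 pair cannot be told apart where they overlap. Control 1 lay between the other controls and the knockdowns for INHBE, at 9.15 FPKM against 25.3 and 31.4 FPKM in controls 2 and 3, and for ISG15, at 191 against 547 and 482 FPKM. It lay with the controls for SAT1, at 170 FPKM against 212 and 170 FPKM, and for TXNIP, at 495 FPKM against 410 and 382 FPKM.

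**Figure D3:**
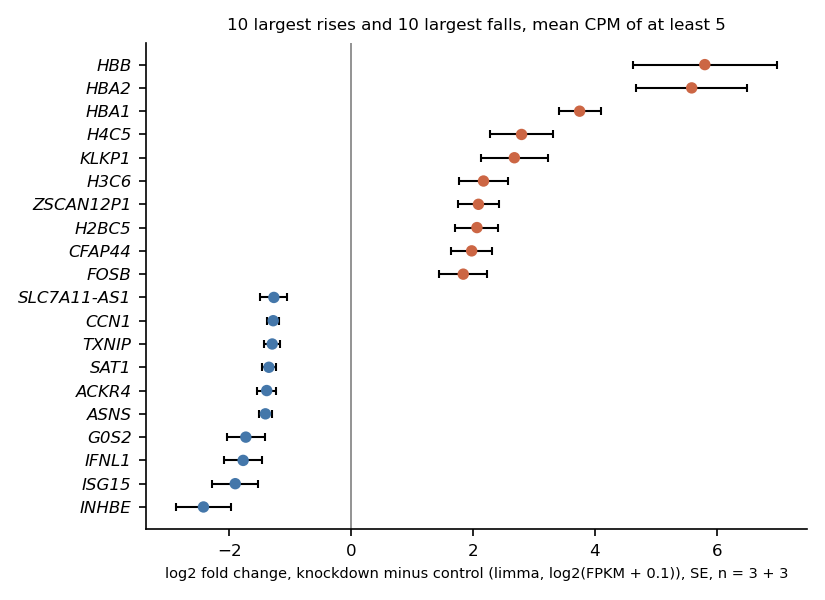
Log2 fold changes, knockdown minus control (x axis), of the 10 largest rises and 10 largest falls among genes past the limma threshold with a mean CPM of at least 5 in the higher group, no overlap between groups and a symbol other than a clone or locus identifier, with bars for the SE (n = 3 libraries per group). Values run from 5.80 for HBB to -2.42 for INHBE.

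Genes of the amino acid and integrated stress response fell as a list. Of 33 members tested, 8 fell, 0 rose and 25 did not pass, and adjusted over the list alone 15 fell and 3 rose. Beside ATF3 and ASNS, the members that fell were SLC7A11, the serine synthesis enzyme PHGDH at -0.65, the transcription factor CEBPG at -0.65, the alanyl-tRNA synthetase AARS1 at -0.57, the mitochondrial folate enzyme MTHFD2 at -0.52, and DDIT4, an inhibitor of mTORC1, at -0.42. Members measured in the other direction without passing included SESN2 at 0.79 and DDIT3, which encodes CHOP, at 0.67 (limma adjusted p of 0.0885 and 0.0978), both chosen after their values were seen. The median over the list was -0.32, and camera gave an adjusted p of 0.000116, against an adjusted p of 0.668 with an estimated correlation. Control 1 was lower than the mean of controls 2 and 3 by a median of -0.30 over the same genes, and the knockdowns differed from control 1 by a median of only -0.08. Without control 1, 21 of the 33 genes fell and 4 rose in limma. The list of endoplasmic reticulum chaperones and unfolded protein response genes had 0 of 23 members past the test, also when adjusted over the list alone, and a median of 0.05 (camera adjusted p = 0.93). Without control 1, 8 of these 23 genes rose and 2 fell in limma, and the median was 0.15.

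Interferon-stimulated genes were lower in the knockdown. Of 28 tested, 2 fell, 0 rose and 26 did not pass, with 2 falls also when adjusted over the list alone. The pair was ISG15 and HERC5, a ligase for ISG15, with log2 fold changes of -1.90 (SE 0.38) and -1.10 (SE 0.22). IRF9 at -0.60 and DDX58, which encodes the RNA sensor RIG-I, at -0.69 did not pass (limma adjusted p of 0.0589 and 0.0664). The list's median was -0.59, with a camera adjusted p of 0.000116 and an adjusted p of 0.668 with an estimated correlation. Control 1 already lay below controls 2 and 3 by a median of -0.95, and the knockdowns differed from control 1 by a median of 0.07. Without control 1, 22 of the 28 genes fell.

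Cytosolic heat shock genes were higher in the knockdown as a list, although 0 of 25 passed the test over all genes and 7 rose when adjusted over the list alone in limma. Among them, the co-chaperones AHSA1 and DNAJA1 had log2 fold changes of 0.55 and 0.94, and HSP90AB1 and HSP90AA1 had 0.80 and 0.65, with adjusted p between 0.052 and 0.0755. The median was 0.74, the camera adjusted p was 0.000372, and the adjusted p with an estimated correlation was 0.668. Control 1 stood with the knockdowns, above controls 2 and 3 by a median of 0.92, and the knockdowns exceeded control 1 by a median of 0.10. HSPA6, a strictly inducible HSP70 chosen after its values were seen, read 161 FPKM in control 1, 0.83 and 1.18 FPKM in controls 2 and 3, and 195, 155 and 161 FPKM in the knockdowns. Without control 1, 23 of the 25 genes rose and 1 fell in limma.

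Blood cell markers, fixed as a check for other cells, were also higher. Of 10 tested, 3 rose, the globin genes HBB, HBA2 and HBA1, and 7 rose when adjusted over the list alone. The median was 1.77 (camera adjusted p = 0.000694, and an adjusted p of 0.53 with an estimated correlation). Of the 18 members, only the 10 with at least 0.5 FPKM in at least 3 libraries were tested. Markers near 0 in the controls could enter through the 3 knockdowns, so the filter favours rises in this list. HBB read 4.03, 2.22 and 61.8 FPKM in controls 1, 2 and 3 and 786, 329 and 400 FPKM in the knockdowns. CD14, a monocyte receptor, had 1.69 and did not pass (limma adjusted p = 0.0527). Among the other foreign cell types, 0 members passed in the lists of Schwann and glial markers (6 tested, median 0.00), fibroblast and endothelial markers (6 tested, median 0.18) and epithelial markers (8 tested, median -0.12), also when adjusted over the list alone, with camera adjusted p of 0.988, 0.945 and 0.376. Without control 1, 0, 0 and 2 members of these lists rose and 1, 0 and 1 fell in limma.

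Upward, 4 further lists passed camera's threshold. In hypoxia and glycolysis, 4 of 31 genes rose, 0 fell and 27 did not pass (7 rose when adjusted over the list alone): the glucose transporter SLC2A1 at 0.80, hexokinase HK2 at 0.79, lactate dehydrogenase LDHA at 0.60 and PGAM1 at 0.29, with a list median of 0.43 and a camera adjusted p of 0.00145. Among 24 p53 target genes, 2 rose, the DNA repair factor XPC at 0.76 and PHLDA3, an inhibitor of AKT, at 0.56 (13 when adjusted over the list alone, median 0.40, camera adjusted p = 0.00701). Among 27 mitosis genes, 3 rose, HMMR at 0.58, the kinetochore protein CENPF at 0.52 and the spindle protein ASPM at 0.48 (12 when adjusted over the list alone, median 0.32, camera adjusted p = 0.00701). Of 15 NF-kB and inflammatory targets, 2 rose, CD83 at 0.64 and NFKB1 at 0.48 (4 when adjusted over the list alone, median 0.38, camera adjusted p = 0.0313). With an estimated correlation the adjusted p was 0.668 for each of the hypoxia, p53 and mitosis lists and 0.53 for NF-kB. Control 1 stood above controls 2 and 3 by medians of 0.40, 0.36 and 0.23 in hypoxia, p53 and mitosis genes and by 0.03 in NF-kB targets. The knockdowns exceeded control 1 by medians of 0.14, 0.17, 0.10 and 0.34 in the same order. Without control 1 the camera adjusted p of the NF-kB list was 0.167. In limma, 21 hypoxia, 18 p53, 19 mitosis and 6 NF-kB genes then rose, and 1, 0, 2 and 0 fell.

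Downward, 3 further lists passed. Of 25 genes of TGF-beta signalling, extracellular matrix and adhesion, 3 fell, all collagen genes: COL5A1 at -0.68, COL6A2 at -0.46 and COL6A1 at -0.44 (11 fell and 2 rose when adjusted over the list alone, median -0.31, camera adjusted p = 0.00145). Among 14 chromosome X neighbours of LINC00894, EOLA2 and IDS, a lysosomal sulfatase, fell (2 when adjusted over the list alone, median -0.21, camera adjusted p = 0.0022). IDS went from 2.39 ± 0.571 to 1.13 ± 0.173 FPKM (SD, n = 3; adjusted p = 0.0499 in limma). MAMLD1, 136842 bases beyond LINC00894, had -0.74 and did not pass (limma adjusted p = 0.111). Among 24 amyloid and tau processing genes, 1 fell, the protease ADAM17 at -0.44 (1 when adjusted over the list alone), while APP, the amyloid precursor, had -0.22 and did not pass (median -0.14, camera adjusted p = 0.0156). With an estimated correlation the adjusted p was 0.53 for the matrix and neighbour lists and 0.668 for amyloid and tau genes. Control 1 lay below controls 2 and 3 by medians of -0.17, -0.35 and -0.16 in the matrix, neighbour and amyloid lists. The knockdowns differed from control 1 by medians of -0.15, -0.12 and -0.04 in the same order. Without control 1, 13, 8 and 8 of their genes fell and 2, 0 and 3 rose in limma.

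The neuronal and survival lists did not pass camera's threshold. In the 13 adrenergic neuroblast genes and the 25 mesenchymal state genes tested, 0 passed, and the medians were 0.19 and -0.08. Of 22 neuronal and synaptic genes, 1 rose, the intermediate filament gene INA at 0.76, and of 18 neurotrophin and survival signalling genes, 1 fell, the receptor gene KIT at -0.58. Among 27 pro-apoptotic genes 0 passed, and among 19 anti-apoptotic genes 1 fell, the kinase PIM1 at -0.57. Camera adjusted p were 0.541, 0.229, 0.46, 0.46, 0.505 and 0.505 in this order. Adjusted over the list alone, these 6 lists held 0, 1, 2, 0, 0 and 0 rises and 0, 3, 3, 1, 0 and 1 falls. Without control 1 they held 4, 5, 4, 2, 9 and 6 rises and 1, 7, 4, 3, 3 and 7 falls in limma. In fry, which tests whether the genes of a list move one way on balance, the adrenergic and pro-apoptotic lists passed upward, with adjusted p of 0.0286 and 0.0299.

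The 9 other lists did not pass camera's threshold either. Of 26 immediate early genes, FOSB, FOSL1 at 0.93 and BTG2 at 0.73 rose and CCN1 fell (6 rose and 3 fell when adjusted over the list alone, camera adjusted p = 0.229). Of 21 NRF2 targets, NQO1 at 0.78, PRDX1 at 0.66 and TALDO1 at 0.26 rose, and SLC7A11, the ferritin gene FTH1 at -0.42 and TKT at -0.39 fell (11 rose and 5 fell when adjusted over the list alone, camera adjusted p = 0.376, fry adjusted p = 0.0179). Of 33 DNA replication genes, RRM2 at -0.39 and E2F1 at -0.37 fell (2 when adjusted over the list alone, camera adjusted p = 0.0738). Among 23 cholesterol synthesis genes 2 rose, NSDHL at 0.47 being one, and SREBF2 at -0.33 fell (2 rose and 2 fell when adjusted over the list alone, camera adjusted p = 0.639). PES1 at 0.56, RRP9 at 0.50 and ODC1 at 0.40 rose and AHCY at -0.45 fell among 23 MYCN and ribosome biogenesis targets (4 rose and 3 fell when adjusted over the list alone, camera adjusted p = 0.835). NDUFB3 at 0.43 and ATP5PB at 0.33 rose among 36 nuclear-encoded oxidative phosphorylation genes (5 when adjusted over the list alone, camera adjusted p = 0.988), and 0 of 40 cytosolic ribosomal protein genes passed (0 when adjusted over the list alone, camera adjusted p = 0.229). Of 13 mitochondrially encoded genes 0 passed, also when adjusted over the list alone, and their median in control 1 was -0.94 against controls 2 and 3, with a camera adjusted p of 0.988 for the group difference. Among 12 RNAs of the library quality list, which lack a poly(A) tail or are highly structured, H1-3 at 2.61 rose and MALAT1 at -1.01 and NEAT1 at -0.44 fell (7 rose and 2 fell when adjusted over the list alone, camera adjusted p = 0.122), and control 1 stood above controls 2 and 3 by a median of 1.53. Without control 1, camera's adjusted p was 0.0187 downward for DNA replication, 0.0217 downward for mitochondrially encoded genes and 0.0121 upward for the library quality list, and without control 3 it was 0.0151 downward for cytosolic ribosomal proteins. Under median-of-ratios scaling it was 0.00894 downward for DNA replication, 0.0104 downward for cytosolic ribosomal proteins and 0.0146 upward for the library quality list. Without control 1, 8 cytosolic ribosomal protein genes rose and 1 fell in limma, and 2 mitochondrially encoded genes rose and 4 fell.

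**Figure D4:**
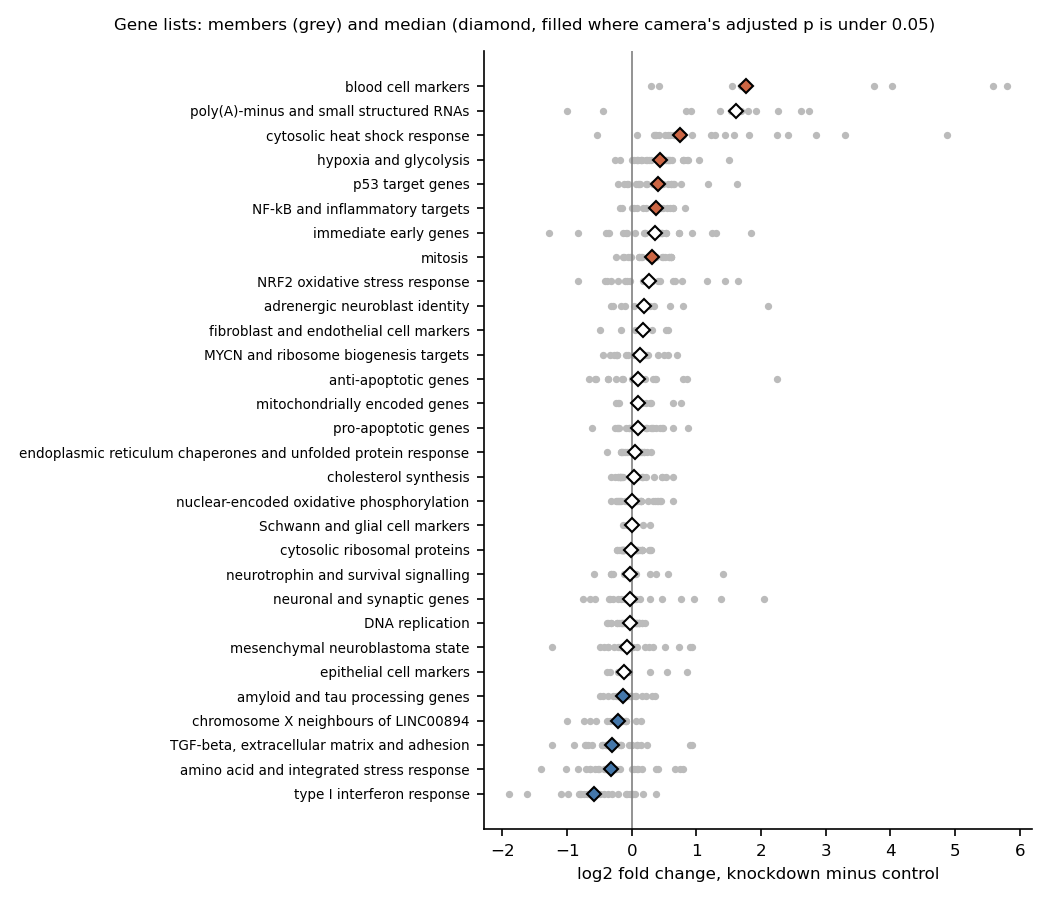
Log2 fold changes, knockdown minus control (x axis), of the tested members of the 30 gene lists (grey points) with the median of each list (diamond, filled where camera's adjusted p was under 0.05). The 11 filled medians run from -0.59 for interferon-stimulated genes to 1.77 for blood cell markers.

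Control 1 stood apart from the other controls. On the first principal component, which held 53.5% of the variance, controls 2 and 3 lay at 64.7 and 66.1, control 1 at -15.7 and the knockdowns at -48.9, -29.8 and -36.4. Across the 18548 genes tested, 60.8% had control 1 nearer to the knockdown mean than to the mean of controls 2 and 3. LINC00894 in control 1 was nonetheless at the level of the other controls.

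**Figure D5:**
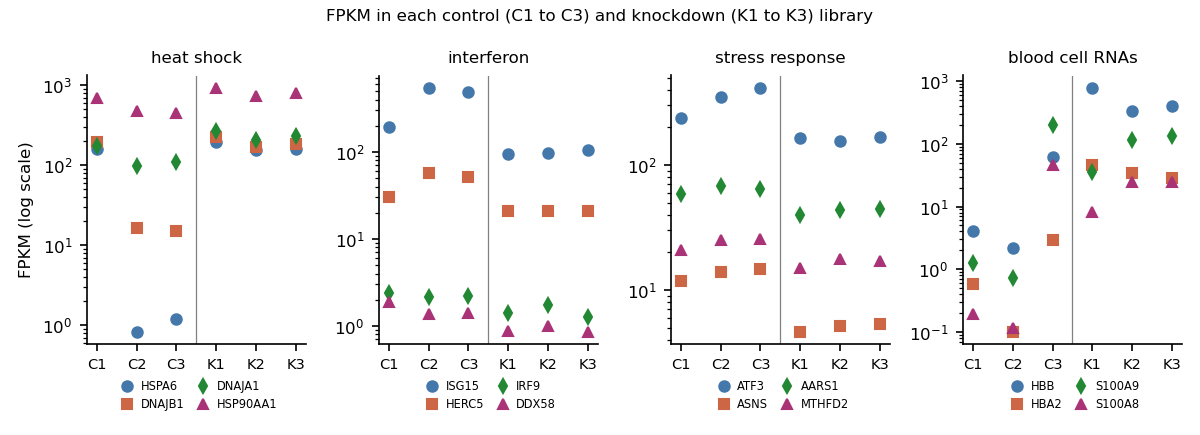
FPKM (y axis, log scale) of 4 genes from each of 4 groups in controls 1 to 3 (C1 to C3) and knockdowns 1 to 3 (K1 to K3), each symbol one gene. HSPA6 reads 161 FPKM in control 1 and 0.83 and 1.18 FPKM in controls 2 and 3, whereas S100A9 reads 202 FPKM in control 3 and 1.25 and 0.726 FPKM in controls 1 and 2.

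The authors' deposited table gives a log2 fold change of -1.11 (adjusted p = 1.17e-06) for LINC00894 and -1.19 (adjusted p = 8.61e-08) for ATF3, on the authors' own counts and test. By p-value, ATF3 ranks 40 and LINC00894 ranks 78 in the authors' deposited table, which is led by TXNIP at -1.41, SAT1 at -1.48 and HBA1 at 3.73. The authors' deposited table of changed genes lists 1867 genes, 1507 higher and 360 lower in the knockdown, all with an unadjusted p under 0.05 and an absolute log2 fold change above 1, and 674 of them have an adjusted p under 0.05. In the authors' deposited table of all genes, 2986 have an adjusted p under 0.05, 1294 higher and 1692 lower. Of these, 2726 were tested here, all with the same sign as in the authors' deposited table, and 837 also passed the limma threshold.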

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

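Pseudocounts of 1 and 0.01, no mean-variance trend, and voom with the same libraries left out or the same block were tried only after the results were seen. LINC00894 and ATF3 kept their direction in every setting run. Their log2 fold changes (main -0.93 and -1.01) ranged from -1.06 to -0.79 and from -1.24 to -0.84 with 1 library left out, and among these settings each passed the limma threshold only without control 1. Their limma adjusted p over all settings ranged from 0.00864 to 0.17 and from 0.00067 to 0.17. With no low-value filter the values were -0.93 and -1.01 (adjusted p 0.0734 and 0.0771), and with no mean-variance trend -0.93 and -1.01 (0.062 and 0.0694). The counts of genes higher, lower and at least 2-fold changed (main 768, 382 and 223) were 25, 17 and 25 with no filter, where more genes were tested, 1426, 659 and 349 with at least 1 CPM in 3 samples, 2295, 835 and 761 with limma-voom, which shared 1091 of the 1150 calls with the same sign, and 65, 26 and 59 with no trend. Under median-of-ratios scaling 338 genes were higher. That scaling uses 1 factor per library and so lowered log2 fold changes by a similar amount across genes. The median moved from 0.07 to -0.05, LINC00894 from -0.93 to -1.05 and ATF3 from -1.01 to -1.14. With a pseudocount of 1 the 2-fold count was 112, and a larger pseudocount shrinks the log2 fold changes of low genes. How much of each drop in count this accounts for was not tested. At an adjusted p under 0.01 the counts were 0, 0 and 0 in limma, whose smallest adjusted p was 0.0237, with 6050 genes at an unadjusted p under 0.05, and limma-voom called 0. With 1 library left out they ranged from 0 to 5187, from 0 to 2906 and from 0 to 1782, the highest without control 1 and 0 without each of the other 5.

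Replicate numbers did not pair the samples: same-numbered deviations correlated at 0.15, 0.08 and 0.04, and not every control correlated best with its own number. With the replicate block limma called 0, 0 and 0 genes (smallest adjusted p 0.0541, 5990 genes at an unadjusted p under 0.05), limma-voom called 3098, and LINC00894 and ATF3 stood at -0.93 and -1.01 (adjusted p 0.0613 and 0.055). Of 30 lists, 28 kept their side of the threshold under the block, and NF-kB targets lost it (adjusted p 0.0761), as they did without control 1 (0.167), while the library quality list gained it (0.0252). Camera called 14 lists under median-of-ratios scaling, 13 without control 1, 12 without control 3 and 12 with no low-value filter, where DNA replication gained a call (0.0168). Camera called 11 lists; 0 passed with an estimated correlation and 6 with fry, and the cause was not tested. Those 6 shared 3 with camera (NF-kB, matrix and blood lists, fry adjusted p 0.0142, 0.0195 and 0.0195), and the other 3 (NRF2, adrenergic and pro-apoptotic genes) had not passed camera. In camera at the preset correlation, 10 of the 11 passed in each of 12 settings with other scaling, filter, pseudocount, block or libraries. Of the other named genes, 17 lost and 4 gained a call under median-of-ratios scaling. Those that lost it were HBB, FOSB, H1-3, HERC5, IDS, INA, ASPM, NFKB1, RRP9, ODC1, TALDO1, LDHA, PGAM1, HK2, SLC2A1, NDUFB3 and ATP5PB. With no low-value filter 57 lost theirs, with no mean-variance trend 55 and under the block 62. Without control 1, 54 gained a call, and 62 lost theirs without each other library. With limma-voom 35 gained one and with at least 1 CPM 24, while a pseudocount of 1 gave 8 gains and one of 0.01 gave 5 losses. The planned edgeR and DESeq2 fits were not run, although whole reads had been recovered, and limma-voom was the only test run on those reads. The deposited unit was FPKM, which already scales by total reads alone. Depth limits low genes: 1 read in a 1 kb model was 0.0437 FPKM in the shallowest library.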

Other observations

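The tests of explanations and the marker lists named here were chosen after the results were seen, whereas the counts over other splits of the libraries were set beforehand. Replication-dependent histone genes were higher in the knockdown: of 35 tested, 14 rose in limma and 0 fell, and 30 rose when adjusted over the list alone, with a median log2 fold change of 2.07. H3C12 reached 3.46 and H2BC14 3.44. Red cell RNAs had 3 rises, the globins, among 10 tested, with 5 rises and 1 fall when adjusted over the list alone (median 0.98). The 7 others did not pass over all genes and went both ways, with log2 fold changes of 2.39 for AHSP, 1.34 for ALAS2, 0.62 for BPGM, 0.08 for FECH, -0.25 for SLC25A37, -0.36 for SELENBP1 and -0.76 for HBQ1. Among 16 neutrophil and monocyte RNAs tested 0 passed (2 rose when adjusted over the list alone, median 2.09), and S100A9 read 1.25, 0.726 and 202 FPKM in controls 1, 2 and 3 and 35.0, 117 and 133 FPKM in the knockdowns. Of 5 lymphocyte RNAs tested 0 passed (2 rose when adjusted over the list alone, median 0.29). In these added lists, too, RNAs near 0 in the controls could pass the filter through the 3 knockdowns, which can raise the medians.

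Heat shock genes stood at the knockdown level in control 1, 0.92 above controls 2 and 3 by median against 1.05 for the knockdowns. A mislabelled knockdown library is argued against by LINC00894, which read 2.00 FPKM in control 1 and at most 1.30 FPKM in the knockdowns. A candidate explanation is a difference in handling or library preparation that control 1 shares with the knockdowns: histone genes were higher in control 1 than in controls 2 and 3 by a median of 1.47, against 2.51 for the knockdowns. An effect of the knockdown on heat shock genes stays open, because only 1 control lies at the knockdown level and the knockdowns exceed it by a median of 0.10. Control 1 had the lowest ATF3 of the controls, although its heat shock genes were raised. Part of the change of ATF3 may go with whatever sets control 1 apart, which was not tested. The knockdowns, at 155 to 167 FPKM, lay below control 1, at 239 FPKM, as well.

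Globin RNAs were higher in the knockdowns, and control 3 had more HBB and HBA2 than the other controls. HBA1 was not raised in control 3. It read 0.368, 0.847 and 0.831 FPKM in controls 1, 2 and 3 and 14.2, 8.62 and 7.99 FPKM in the knockdowns. RNA or reads from blood cells may be a source: of 19 neutrophil and monocyte RNAs, leaving out the 3 S100 genes that prompted the test, 17 were higher in control 3 and in every knockdown than in controls 1 and 2. The most abundant were S100A9 and HBB, at 202 and 61.8 FPKM in control 3, and controls 1 and 2 both expressed 0 of 22 neutrophil and monocyte, 6 of 18 red cell and 2 of 24 lymphocyte RNAs at 1 FPKM or more. An effect of the knockdown on blood cell genes stays open, since only 1 control is raised, by a median of 2.91 over 22 neutrophil and monocyte RNAs against 2.73 for the knockdowns. The ratio of HBB to S100A9 differed between these libraries, at 786 to 35.0 FPKM in knockdown 1 and 61.8 to 202 FPKM in control 3.

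For the histone genes, more cells in S phase is argued against by 33 DNA replication genes, whose median log2 fold change was -0.03 (SE 0.04). Each SE in this paragraph is taken over the genes of a set, which share the same 6 libraries, and not over libraries. The DNA replication median was -0.15 under median-of-ratios scaling and -0.10 without control 1. Short gene models are argued against as the whole cause by 93 other protein-coding genes no longer than the median histone model of 787 bases, whose median was 0.13 (SE 0.13). More carry-over of RNA without a poly(A) tail remains a candidate explanation. Over 10 small structured RNAs the median was 1.67 (SE 0.61), and 7 of 16 measured had all 3 knockdowns above controls 2 and 3. The filter admitted RNAs absent from controls 2 and 3 through control 1 and the knockdowns, which can raise this median. RNU4-1, for example, read 0.727, 0 and 0 FPKM in controls 1, 2 and 3 and 0.619, 0.501 and 0.493 FPKM in the knockdowns. The median rests in part on such low values. The count of 7 leaves out control 1, which stood at or above the knockdown level for some of these RNAs. RNU6-1 read 20200 FPKM in control 1 and between 4560 and 5930 FPKM in the knockdowns. In controls 2 and 3 it read 16.3 and 30.3 FPKM. RN7SL3 in control 1 was below every knockdown, at 8.68 FPKM against 10.6 to 21.8 FPKM. MALAT1, which lacks a poly(A) tail, fell by 1.01 on the log2 scale (limma adjusted p = 0.0335). NEAT1, whose long form lacks one, fell by 0.44 (limma adjusted p = 0.0379). MALAT1 averaged 186 FPKM in the controls, and how these long RNAs entered the libraries was not tested. Their fall therefore does not decide for or against carry-over. A biological effect of the knockdown on histone transcripts was not separately tested.

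With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1150 genes, 223 of them at least 2-fold apart, and the highest other split gave 0 and 0 in limma, so 1 of the 10 splits reached each count; the other splits had between 116 and 2313 genes at an unadjusted p under 0.05. For gene lists, 3 of the 10 splits, the real one included, gave at least 11 lists, and the highest other split gave 12. The other splits with 10 to 12 lists each set controls 2 and 3 together against control 1, which points to a structure of the samples.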
